A study of Homo sapiens with 12 samples.

How the data were processed

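The series holds 12 RNA-seq libraries from U87-MG, a human glioblastoma line. The labels put them in 4 groups of 3 libraries: wild-type (WT) cells and cells without LATS1 and LATS2 (KO), each untreated or given class 3 semaphorin. Per the labels' protocols, cells grew in DMEM with serum and received recombinant SEMA3A at 500 ng/ml for 6 hours, while the treatment label and the series text say SEMA3s, so the ligand is written SEMA3 here. Per the labels' protocols, total RNA was taken with TRIzol and libraries were made with an Illumina TruSeq Stranded mRNA kit, from index set A or set B. Which set served which library is not given in the sources used here, nor is the method or clone behind the KO cells. The series text speaks of biological replicates, and n = 3 in each group throughout.

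Per the submitters' processing notes, the authors used STAR 2.4.2a, Cufflinks 2.2.1 and the hg19 genome build. The annotation release and the strand setting are not given in the sources used here. The authors deposited 1 gene-level Cufflinks table per library with FPKM (fragments scaled by transcript length and by all mapped fragments), its confidence bounds and a status, per the file headers. Each table has 60350 lines. The values were taken as deposited, with no further scaling. The deposited tables hold no counts, and no count test was run.

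The depth of each library is unknown, but the confidence bounds in the tables depend on it. In genes with an FPKM from 1 to 5, the median distance from the value to its bound was 19.5% to 23.6% of the value across libraries. It was 7.40% to 8.50% for an FPKM from 5 to 50 and 4.26% to 4.61% above 50. From these bounds the depth of each library relative to the others was estimated as 0.877 to 1.155, a median over 11817 genes.

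Cufflinks gave the status HIDATA (more fragments at a locus than it would process) or FAIL to some genes, and lists these at 0. In all, 43 lines had such a status in at least 1 library, 22 as HIDATA and 21 as FAIL, and were left out. HIDATA occurred in 7 libraries, which were deeper by the estimate above: WT untreated 1 and 2, WT SEMA3 2, KO untreated 1, and KO SEMA3 1, 2 and 3. With these lines left out, the correlation of log values between libraries was 0.9858 to 0.9932 within a group, 0.9863 to 0.9917 between treatments of one genotype and 0.9699 to 0.9821 between genotypes. The libraries therefore separate by genotype and not by treatment on this measure. KO untreated 3 had the lowest correlations with its own group, 0.9858 and 0.9871. No pair of libraries was identical.

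FPKM values of lines with one gene symbol were summed, which touched 92 tested symbols. Genes with an FPKM of at least 1 in at least 3 libraries were tested, 13223 in all. Values were log2(FPKM + 1), so a log2 change understates the change of genes with low values. One linear model with a mean for each of the 4 groups was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with a trend. The contrasts tested were SEMA3 against untreated in WT and in KO, the difference between these 2 effects (WT minus KO, the interaction), and KO against WT without and with SEMA3. Every adjusted p for a gene is limma's, after Benjamini-Hochberg adjustment over all 13223 genes, with a threshold of 0.05. Where a count is given as adjusted over the list alone, the adjustment ran over the members of that list. Values given with ± are SDs of FPKM, and SE is the standard error of a log2 change.

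In all, 25 gene lists were fixed, and 23 had at least 3 tested members. These 23 were tested with camera (limma) at its preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation and with fry. The choices of test, filter, lists and named genes, and the alternatives except those said to be added, were made before the data were examined. The genes named are the LATS1/2, YAP/TAZ and receptor genes given for every contrast, the 8 genes with the largest rise and the 8 with the largest fall past the threshold, and up to 4 members of a list. The 8 were taken among genes with a mean FPKM of at least 5 in the higher group and no overlap between the groups, which was not asked of the interaction. Antisense, LOC, LINC, MIR, SNOR and pseudogene-like symbols were left out. The pattern for small RNA symbols was tightened after values had been seen, because a ribosomal RNA pseudogene had passed it. Some genes that this rule names are not reported here. Markers of cell types are given as FPKM by a separate rule, and other genes named outside these rules are said to be so. Transcript length, GC content and gene type came from the GENCODE 29 annotation of GRCh38, matched by Ensembl gene identifier, and were found for 13093 of the 13223 genes. Coordinates are those of the deposited tables (hg19).

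The alternatives were a pseudocount of 0.1, no filter or an FPKM minimum of 5, median-ratio scaling, quantile normalization, the replicate number as a block, limma's array weights, no variance trend, only the groups compared, symbols not summed, failed estimates kept, and each library left out in turn. Added after the data were seen were a term for the 7 libraries with HIDATA, the removal of each library's trend on transcript length and GC content, and leaving out small RNA genes. On simulated data for the SEMA3 comparison in WT with 13223 genes, the fit recovered 89 of 100 genes changed 1.5-fold and 98 of 100 changed 2-fold, with 10 false calls among 197. For the interaction, again over 13223 genes, it recovered 63 and 96 of 100, with 5 false calls among 164. The changed genes were drawn only from those with an average FPKM above about 5, and the noise was independent between genes. These rates therefore do not cover genes with lower values or shifts that many genes of a library share. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.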

Results

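Messenger RNA of U87-MG glioblastoma cells was measured in 12 libraries: 3 of untreated WT cells, 3 of WT cells given SEMA3, 3 of untreated KO cells and 3 of KO cells given SEMA3. The series title places semaphorin signaling upstream of the Hippo pathway, in which the kinases LATS1 and LATS2 restrain the transcriptional coactivators YAP and TAZ. The design asks what SEMA3 changes in WT cells, what it changes in cells without LATS1/2, and whether these responses differ. FPKM totals were 562391 to 607767 per library, and 12644 to 12861 genes reached an FPKM of 1.

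The targeted genes kept transcripts in the KO libraries. LATS1 (chromosome 6, 149979289 to 150039392) had FPKM values of 4.79, 5.09 and 4.80 in untreated WT, 4.64, 3.91 and 4.34 in WT with SEMA3, 4.19, 4.12 and 4.71 in untreated KO, and 4.27, 4.40 and 4.17 in KO with SEMA3. LATS2 (chromosome 13, 21547171 to 21635686) had 2.74, 2.88 and 2.76 in untreated WT and 2.48, 2.14 and 2.38 in WT with SEMA3. It had 3.83, 4.02 and 3.6 in untreated KO and 3.43, 3.56 and 3.53 in KO with SEMA3. LATS1 did not differ past the threshold between genotypes (log2 -0.14, adjusted p = 0.12 untreated, and 0.00, adjusted p = 0.99 with SEMA3). SEMA3 did not move LATS1 (-0.16, adjusted p = 0.17) or LATS2 (-0.19, adjusted p = 0.088) past the threshold in WT. LATS2 was higher in KO, by 0.34 (SE 0.06, adjusted p = 0.0012) and 0.44 (SE 0.06, adjusted p = 0.00021). A gene-level FPKM does not check an edit that leaves the transcript in place, so these values neither support nor oppose the KO labels.

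In WT cells, 6 hours of SEMA3 lowered the best known YAP/TAZ target genes. CYR61 (chromosome 1, 86046444 to 86049645), which encodes a secreted matricellular protein, fell from 28.5 ± 1.5 to 13.3 ± 0.23 FPKM (n = 3 each), a log2 change of -1.05 (SE 0.04, adjusted p = 3.8e-07). CTGF (chromosome 6, 132269316 to 132272513), of the same protein family, fell from 14.1 ± 0.37 to 7.49 ± 0.29 (-0.84, SE 0.04, adjusted p = 2.8e-06). AMOTL2, an angiomotin family gene, fell from 23.4 ± 0.82 to 15.6 ± 0.13, the receptor tyrosine kinase gene AXL from 121 ± 7.4 to 94.6 ± 1.4, and ANKRD1 by 0.53 on the log2 scale (adjusted p = 0.0071). YAP1 (-0.03, adjusted p = 0.86) and WWTR1, the TAZ gene (-0.02, adjusted p = 0.89), did not pass the threshold, nor did the semaphorin receptor genes NRP1 (-0.05, adjusted p = 0.54), NRP2 (-0.17, adjusted p = 0.051) and PLXNA1 (-0.04, adjusted p = 0.80). Among the genes that rose, the kinetochore genes CENPF (chromosome 1, 214776538 to 214837931) and CENPE went from 43.2 ± 2.2 to 87.6 ± 5.1 and from 12.2 ± 1.6 to 25.4 ± 1.1 FPKM, both with a log2 change of 1.0.

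**Figure D1:**
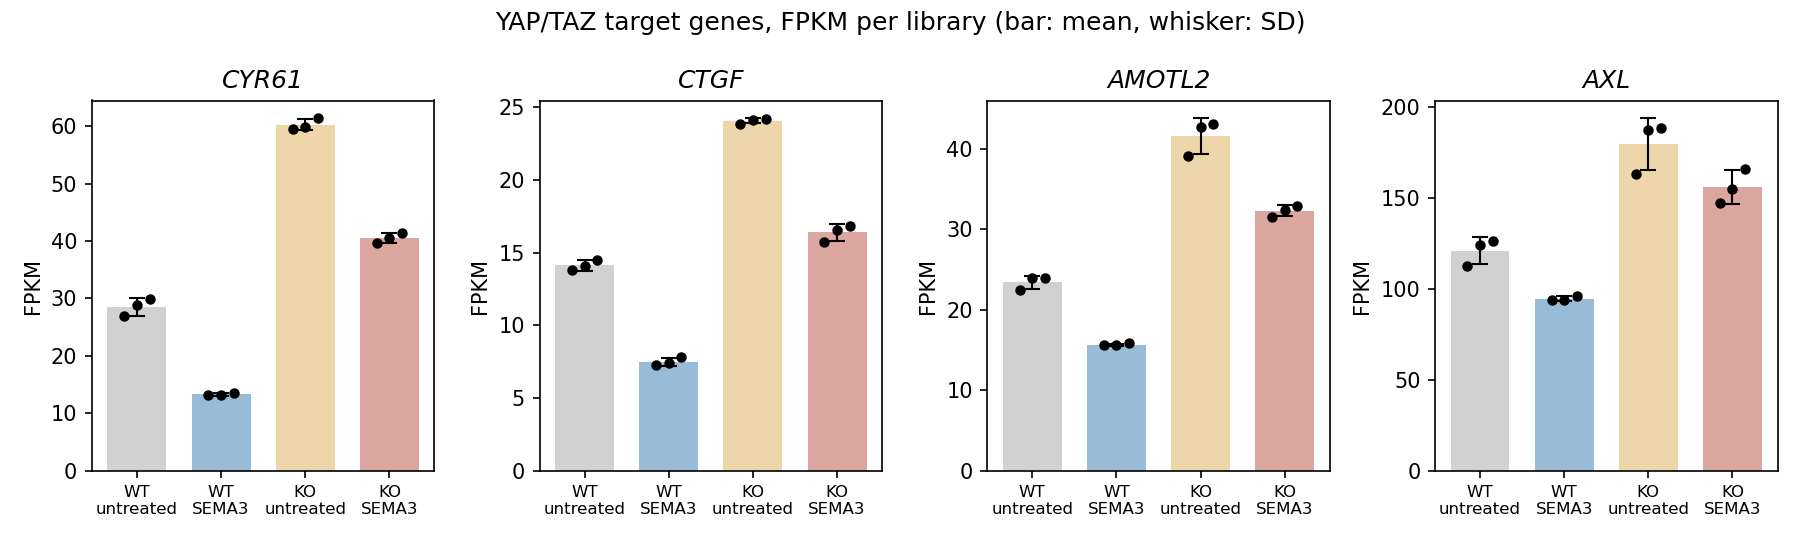
FPKM of CYR61, CTGF, AMOTL2 and AXL in the 4 groups. Points are libraries, bars are means and whiskers are SDs (n = 3). SEMA3 lowered the mean in both genotypes, and KO cells with SEMA3 stayed above untreated WT cells: 40.5 against 28.5 for CYR61.

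Of 33 tested YAP/TAZ target genes, 17 fell and none rose in WT cells with SEMA3 (24 lower and 1 higher when adjusted over the list alone), and camera gave an adjusted p of 8.69e-18 (adjusted p = 0.00141 with an estimated correlation). DLC1 fell by 0.67 and the keratin gene KRT34 by 0.81. Of 25 SRF/MRTF cytoskeletal target genes, 9 fell and none rose (12 lower when adjusted over the list alone), among them VCL (-0.46), CNN2 (-0.43) and TPM1, from 439 ± 9.1 to 334 ± 5.1 FPKM. Camera gave 1.14e-07 for this list, but adjusted p = 0.163 with an estimated correlation. Of 35 Hippo pathway components, 6 fell, among them FRMD6 (-0.56) and AJUBA (-0.34). Adjusted over the list alone, 8 were lower and 1 higher (camera adjusted p = 0.0117, and adjusted p = 0.336 with an estimated correlation). Of 53 G2/M cell cycle genes, 14 rose and 1 fell (17 and 2 when adjusted over the list alone), led by CENPE, CENPF, KIF20B (0.84) and SMC4 (0.47). Camera gave 3.83e-06, and adjusted p = 0.211 with an estimated correlation. No other tested list passed camera in this comparison.

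Further large falls in WT were the WNT antagonist gene DKK1 from 21.7 ± 1.2 to 12.6 ± 0.23 (-0.74, adjusted p = 0.00011), MAFF (-0.70) and the noncoding RP11-553A10.1 (-0.68). AL590369.1, which the GENCODE 29 annotation lacks, fell by 2.31 (SE 0.61, adjusted p = 0.040), a call lost in 9 of 12 fits that left out 1 library (adjusted p = 0.127 without WT untreated 1). The largest rises also held BRCA2 (0.97), AKAP9 (0.96), ASPM (0.86), MXD3 (1.0), SCAND1 (0.96) and CCDC85B (0.90). The MXD3 and CCDC85B calls were lost without WT SEMA3 3 (adjusted p = 0.0681 and 0.0837) and in 2 and 3 other such fits, and SCAND1 was lost in 10 fits (adjusted p = 0.151 without WT untreated 1). MXD3, SCAND1 and CCDC85B also varied widely among the untreated KO libraries, from 6.42 to 14.59, 5.68 to 16.26 and 6.81 to 14.66 FPKM.

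In all, 1103 of 13223 genes passed the threshold in WT, 555 higher and 548 lower with SEMA3, against 3393 at an unadjusted p under 0.05. The count was 2124 without KO untreated 3, and 504, 653, 597 and 465 without WT untreated 1, WT untreated 2, WT SEMA3 2 and WT SEMA3 3. It was 694 with no filter and 3879 with array weights. The near-even balance became 492 higher and 668 lower after median-ratio scaling, and 1277 and 847 without KO untreated 3.

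In KO cells, SEMA3 lowered the same leading YAP/TAZ target genes. CYR61 fell from 60.3 ± 0.99 to 40.5 ± 0.90 FPKM (-0.56, SE 0.04, adjusted p = 4e-04), CTGF from 24.1 ± 0.18 to 16.4 ± 0.57 (-0.53, adjusted p = 5e-04), AMOTL2 from 41.6 ± 2.2 to 32.3 ± 0.68 (-0.35, adjusted p = 0.0030) and DLC1 by 0.53. ANKRD1 (-0.29, adjusted p = 0.18) and AXL (-0.20, adjusted p = 0.15) did not pass. Nor did LATS1 (-0.01, adjusted p = 0.96), LATS2 (-0.10, adjusted p = 0.51), YAP1 (0.06, adjusted p = 0.76), WWTR1 (-0.03, adjusted p = 0.91), NRP1 (-0.01, adjusted p = 0.94), NRP2 (-0.17, adjusted p = 0.11) and PLXNA1 (-0.06, adjusted p = 0.79). Rises were led by RGS2, a regulator of G protein signaling, from 4.28 ± 0.43 to 7.19 ± 0.17 FPKM (0.64, adjusted p = 0.00095), ID2, an inhibitor of basic helix-loop-helix factors, from 58.8 ± 4.2 to 87.3 ± 1.2 (0.56, adjusted p = 0.0019), and RIMS3 from 4.46 ± 0.075 to 6.78 ± 0.059 (0.51, adjusted p = 0.00059). SLC7A8 (0.52), ARRDC3 (0.49), TRIB2 (0.48), BEGAIN (0.47) and IFITM10 (0.45) also rose. The largest falls were GOLGA4, a golgin gene, from 27.7 ± 1.3 to 17.3 ± 1.5 FPKM (-0.65, adjusted p = 0.0014), CCDC88A (-0.65), EEA1 (-0.64), RIF1 (-0.64), TRIP11 (-0.63), RP11-618G20.1 (-0.63) and IGF2BP2 (-0.79, adjusted p = 0.047). IGF2BP2 was lost in 10 fits that left out 1 library, RP11-618G20.1 in 6, CCDC88A and BEGAIN in 3, EEA1 and IFITM10 in 2 and ARRDC3 in 1, each with the highest adjusted p (0.153, 0.139, 0.0626, 0.0749, 0.0646, 0.0626 and 0.0549) without KO SEMA3 1.

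Of the 33 YAP/TAZ target genes, 8 fell and none rose in KO cells (17 lower when adjusted over the list alone; camera adjusted p = 8.05e-17, and adjusted p = 0.00172 with an estimated correlation). KRT34 (-0.43) lost its call without any 1 of the KO libraries except KO untreated 3 (adjusted p = 0.110 without KO SEMA3 3). Of 25 SRF/MRTF target genes, 4 fell, led by CALD1 (-0.47), with 7 lower when adjusted over the list alone (camera adjusted p = 4.05e-06, and adjusted p = 0.21 with an estimated correlation). Of 35 Hippo components, 3 fell (4 over the list alone), FRMD6 (-0.41) and AMOTL2 among them (camera adjusted p = 0.000112, and adjusted p = 0.21 with an estimated correlation). The 30 unfolded protein and ATF4 response genes had no member past the threshold, but 28 of them lay above 0, and camera gave 0.000514 (adjusted p = 0.0454 with an estimated correlation). Small upward shifts with no member past the threshold were also seen in 45 nuclear-encoded respiratory chain genes (median 0.103, camera adjusted p = 2.2e-08) and 63 cytosolic ribosomal protein genes (median 0.084, camera adjusted p = 8.89e-07). With an estimated correlation these had adjusted p = 0.21 and adjusted p = 0.38. Short transcripts as a whole lay above 0 in this comparison: the 445 genes with the shortest had a median of 0.075 and the next 1967 one of 0.058, or 0.028 and 0.013 with the length and GC trend removed. Camera gave 0.274 for the cytosolic ribosomal protein genes after quantile normalization and 0.193 with the HIDATA term.

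Of 34 extracellular matrix genes, 3 rose in KO cells, MMP3 (0.41), THBS2 (0.28) and COL1A2 (0.22), and 9 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00995, and adjusted p = 0.368 with an estimated correlation). Without KO untreated 3 camera gave 0.157, and without KO SEMA3 2 it gave 0.0985. Of 31 hypoxia and glycolysis genes, DDIT4 (0.43), PFKFB4 (0.26) and HK2 (0.26) rose, 3 also when adjusted over the list alone (camera adjusted p = 0.0111, and adjusted p = 0.38 with an estimated correlation), and camera gave 0.239 without KO untreated 3 and 0.0571 without KO SEMA3 2. Of 26 immediate early genes, DUSP5 fell (-0.25), with 2 higher and 6 lower over the list alone (camera adjusted p = 0.00946, and adjusted p = 0.38 with an estimated correlation), and camera gave 0.0656 and 0.0931 without KO untreated 1 and 2. THBS2, DDIT4, PFKFB4 and DUSP5 lost their calls in 5, 9, 8 and 6 of the fits that left out 1 library, with adjusted p up to 0.121 and 0.153 without KO SEMA3 3, 0.121 without KO SEMA3 2 and 0.104 without KO untreated 2. COL1A2 lost its call in 2 (0.0753 without KO SEMA3 1).

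In all, 283 genes passed the threshold in KO, 106 higher and 177 lower, against 2001 at an unadjusted p under 0.05. The 177 had a median transcript length of 4995 bases and a GC content of 39.6%, against 3082 bases and 48.1% over all tested genes. The count was 185 and 109 without KO untreated 1 and 2, 82, 139 and 102 without KO SEMA3 1, 2 and 3, and 179 without WT SEMA3 3. It was 21 in a fit of the 6 KO libraries alone. With array weights 1220 genes passed and the balance turned, with 663 higher and 557 lower.

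The responses of both genotypes, which share no library but share a common estimate of the spread per gene, overlapped in part. Genes with a small spread are called more readily in both, so the counts for independent lists below are only a rough reference. Of the 555 genes higher with SEMA3 in WT and the 106 higher in KO, 46 were shared, against 4.4 for independent lists. Of the 548 and 177 lower genes, 60 were shared, against 7.3. The shared rises held RGS2 (0.46 in WT), ID2 (0.39), RIMS3 (0.34), ARRDC3 (0.48), TRIB2 (0.41) and IFITM10 (0.52). The shared falls held CYR61, CTGF, DLC1, FRMD6, AMOTL2, MAFF (-0.42 in KO) and RP11-553A10.1 (-0.60). Another 63 genes were higher in WT and lower in KO, while 1 went the other way. Of the 555 genes higher in WT, 262 lay above 0 in KO, and of the 548 lower ones, 459 lay below 0. Across all 13223 genes, which are not independent replicates, the 2 effects had a Pearson r of 0.023 and a Spearman correlation of 0.182.

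The interaction tested directly whether SEMA3 changed a gene differently in WT and KO. It set apart genes that rose in WT and fell in KO: CENPF (43.2 to 87.6 FPKM in WT, 92.7 ± 5.3 to 65.3 ± 0.52 in KO, difference of log2 changes 1.5, SE 0.08, adjusted p = 4.5e-06), CENPE (1.58), GOLGA4 (1.5), ATRX, a chromatin remodeler gene (1.41), KIF20B (1.40), the spindle gene ASPM (1.34), ANKRD12 (1.34) and DST, a cytoskeletal linker gene (40.7 ± 1.9 to 72.4 ± 1.5 in WT, 76.4 ± 3.7 to 55.9 ± 2.6 in KO, 1.26). In the opposite direction, CYR61 fell more on the log2 scale in WT than in KO (-0.49, SE 0.06, adjusted p = 0.0013). MMP3, a matrix metalloproteinase gene, went from 206 ± 2.6 to 181 ± 4.3 FPKM in WT and from 59.8 ± 3.9 to 79.8 ± 1.3 in KO (-0.60, adjusted p = 0.00034). F2R, a thrombin receptor gene, went from 13.4 ± 0.24 to 11.9 ± 0.38 in WT and from 35.7 ± 2.8 to 44.8 ± 0.73 in KO (-0.48, adjusted p = 0.0052), and APLN had -0.47 (adjusted p = 0.0041).

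**Figure D2:**
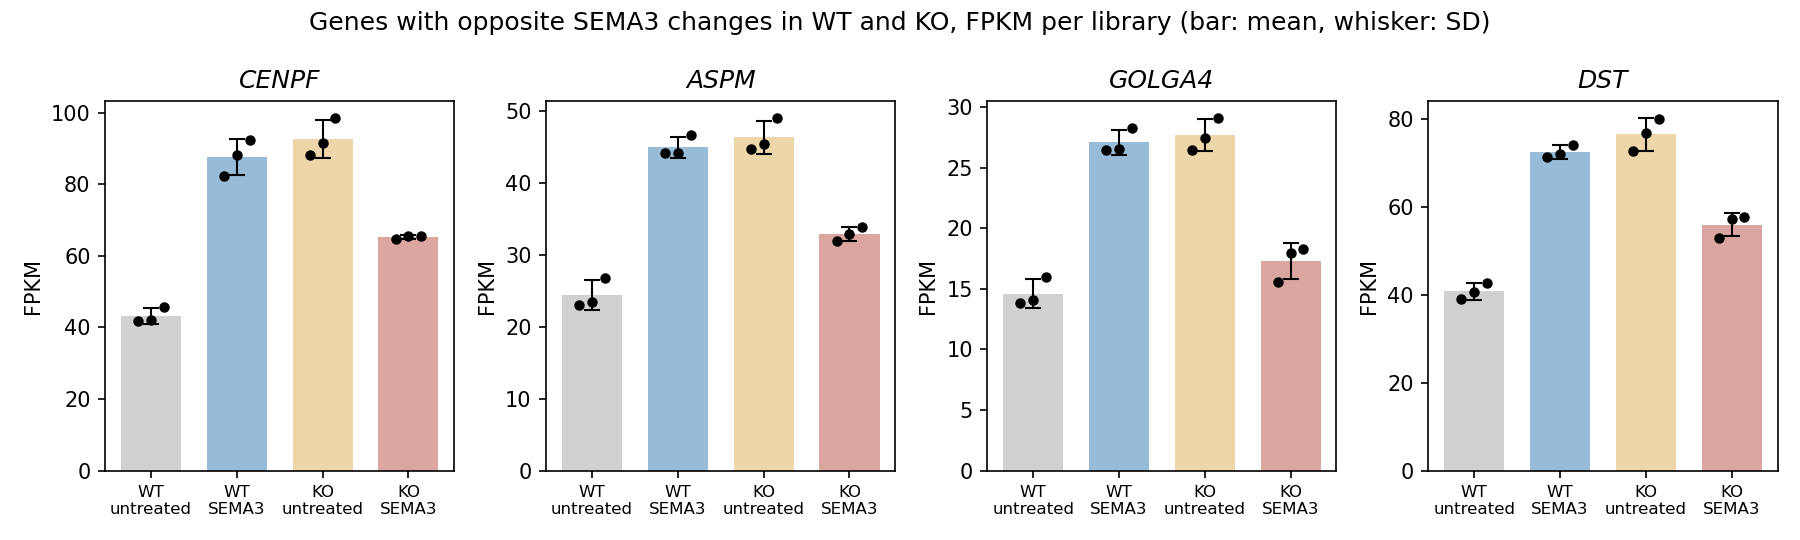
FPKM of CENPF, ASPM, GOLGA4 and DST in the 4 groups. Points are libraries, bars are means and whiskers are SDs (n = 3). In each gene SEMA3 raised the mean in WT and lowered it in KO, as for DST from 40.7 to 72.4 and from 76.4 to 55.9.

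Of the 33 YAP/TAZ target genes, 4 had a larger log2 fall in WT past the threshold, among them CYR61, CTGF (-0.31, adjusted p = 0.026) and CRIM1 (-0.27, adjusted p = 0.038). Adjusted over the list alone, 8 were lower and 1 higher. The median was -0.125 and camera gave 0.00162, but adjusted p = 0.246 with an estimated correlation. Fry gave an adjusted p of 0.0111. CTGF and CRIM1 lost their calls in 8 and 9 of the 12 fits that left out 1 library (up to adjusted p = 0.0823 without WT SEMA3 3 and 0.110 without WT untreated 1), while CYR61 kept its call in each. AMOTL2 (-0.20, adjusted p = 0.17), AXL (-0.15, adjusted p = 0.47) and ANKRD1 (-0.24, adjusted p = 0.43) did not pass, nor did LATS1 (-0.14), LATS2 (-0.09), YAP1 (-0.09), WWTR1 (0.01), NRP1 (-0.04), NRP2 (-0.01) and PLXNA1 (0.02). Over all 33 target genes the median change was -0.239 in WT and -0.168 in KO, and 25 of the 33 had an interaction below 0. The 17 that fell in WT all lay below 0 in KO.

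**Figure D3:**
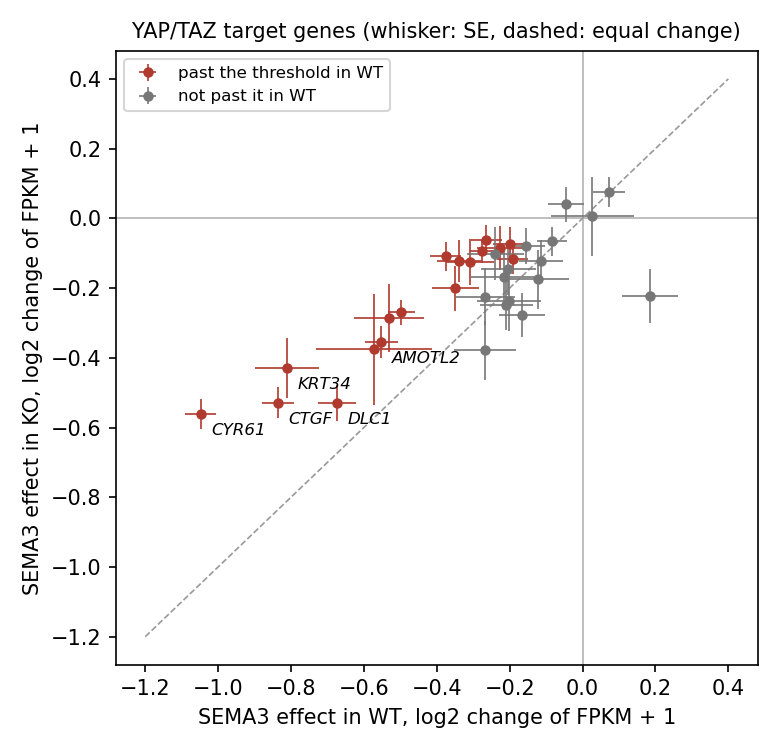
Log2 change of FPKM + 1 with SEMA3 in WT (horizontal axis) and KO (vertical axis) for 33 YAP/TAZ target genes, with SE whiskers and a dashed line of equal change. The 17 genes past the threshold in WT are red and lie below 0 on both axes. They were picked for their change in WT, so their place above the line does not test a smaller change in KO.

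Of 53 G2/M genes, 10 had a more positive response in WT and none a more negative one (16 and 1 when adjusted over the list alone), SMC4 (0.78) among them, although the list's median was 0.027. Camera gave 0.00162, and adjusted p = 0.545 with an estimated correlation, and camera gave 0.154 without KO untreated 3. Extracellular matrix genes had a median of -0.108, with MMP3 past the threshold among 34 and 6 lower over the list alone (camera adjusted p = 0.00211, and adjusted p = 0.545 with an estimated correlation). Without KO untreated 3 camera gave 0.154. TGF-beta target genes had a median of -0.102, with 3 lower among 22, TGFBI (-0.34) and CTGF among them, and 5 lower over the list alone (camera adjusted p = 0.0239, and adjusted p = 0.545 with an estimated correlation). Camera gave 0.514, 0.0623 and 0.0917 for this list without KO untreated 3, WT untreated 2 and WT SEMA3 1, and TGFBI was lost in 2 fits (adjusted p = 0.0565 without WT SEMA3 3). The SRF/MRTF target list did not pass (camera adjusted p = 0.156), but 2 of its 25 genes were lower and none higher. TPM1 (-0.37, adjusted p = 0.00083) fell by 105 FPKM in WT and 8.3 in KO. FHL2 (-0.27, adjusted p = 0.019) fell by 47.7 and 12.9 FPKM, and its call was lost in 6 fits that left out 1 library.

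Further falls in the interaction were RP11-905K4.1 (-0.63, adjusted p = 0.048), HHIPL2 (-0.52, adjusted p = 0.029), BTBD11 (-0.50, adjusted p = 0.039) and DKK1 (-0.49, adjusted p = 0.022). These lost their calls in 10, 8, 9 and 6 fits that left out 1 library, with adjusted p up to 0.123 and 0.115 for RP11-905K4.1 and BTBD11 without WT untreated 1, 0.0855 for HHIPL2 without KO SEMA3 1 and 0.0651 for DKK1 without WT untreated 2.

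In all, 291 genes passed the interaction test, 248 more positive in WT and 43 more negative, against 1986 at an unadjusted p under 0.05. The 248 had a median transcript length of 5812 bases and a GC content of 37.7%, against 3082 bases and 48.1% over all tested genes. The count was 1240 without KO untreated 3, and 170, 163, 191 and 182 without KO SEMA3 1, WT untreated 1, WT SEMA3 1 and WT SEMA3 3. It was 144 with a term for the libraries with HIDATA, which were 2 of 3 in untreated WT, 1 in WT with SEMA3, 1 in untreated KO and 3 in KO with SEMA3. With the length and GC trend removed, 381 genes passed and 67.5% of them were more positive in WT, against 85.2%. This share was 53.3% of 2514 genes with array weights and 69.5% of the 1240 without KO untreated 3.

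**Figure D4:**
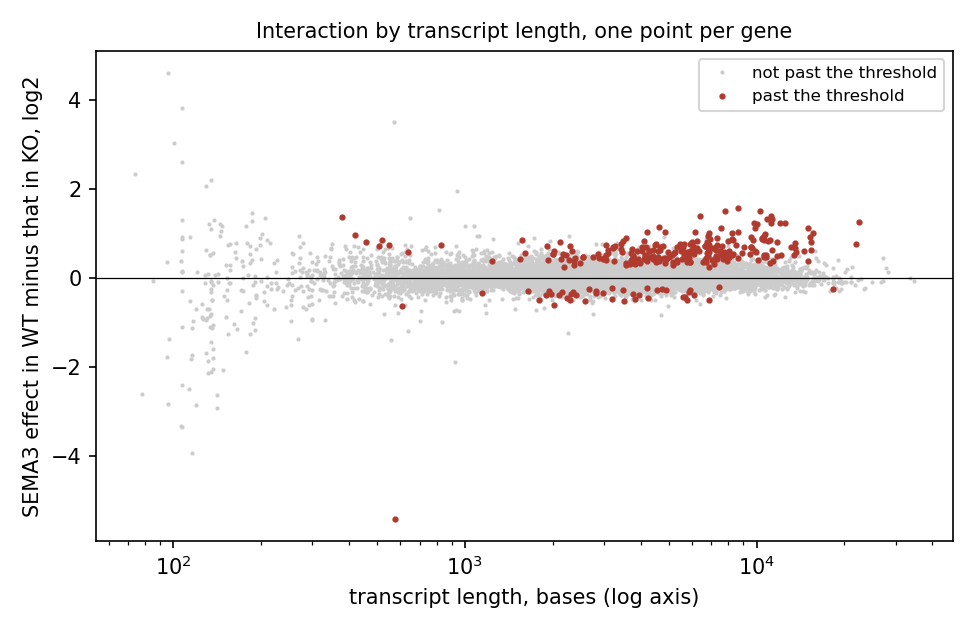
Interaction (log2 change with SEMA3 in WT minus that in KO) against transcript length in bases on a log axis, 1 point per gene, with genes past the threshold in red. The lowest point is CH17-478G19.2, named here after its value was seen, an unprocessed pseudogene in GENCODE 29 whose reads a near copy can share.

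Without SEMA3, KO cells had more of the YAP/TAZ target transcripts and less of many inflammatory ones than WT cells. CYR61 was 60.3 against 28.5 FPKM (1.05, SE 0.04, adjusted p = 9.4e-09), CTGF was higher by 0.73, AMOTL2 by 0.80, AXL by 0.57 and ANKRD1 by 0.50 (adjusted p = 0.0019), whereas WWTR1 was lower (-0.47, adjusted p = 0.0004) and YAP1 (0.08, adjusted p = 0.47), NRP1 (0.04), NRP2 (-0.09) and PLXNA1 (-0.09) did not pass. The activin antagonist gene FST was 41.4 ± 2.0 against 7.34 ± 0.40 FPKM (2.35, adjusted p = 1.2e-09), the imprinted gene MEST 115 ± 7.1 against 22.8 ± 2.7 (2.29) and RGS4 59.1 ± 1.3 against 13.7 ± 1.4 (2.03). UCA1 (2.14), CHRDL1 (1.97), DKK1 (1.72), PPP2R2B (1.62) and FZD7 (1.55) were also higher. Complement C3 was 3.37 ± 0.72 in KO against 51.6 ± 1.5 FPKM in WT (-3.6, adjusted p = 1.2e-09), and ITGAX (-2.54), CALB2 (-2.13), LCP1 (-2.06), the cytokine gene CSF3 (-1.99), AKR1C1 (-1.93), C4orf26 (-1.89) and podoplanin gene PDPN (-1.88) were lower.

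Of 33 YAP/TAZ target genes, 21 were higher and 2 lower in untreated KO cells, over all genes and when adjusted over the list alone, among them IGFBP3 (39.7 to 106 FPKM, 1.39) and DLC1 (1.18). Camera gave 2.88e-10, and adjusted p = 0.00851 with an estimated correlation. Of 23 NF-kB and inflammatory genes, 16 were lower and 1 higher by both adjustments, among them CXCL8 (29.3 ± 1.0 to 9.18 ± 0.99 FPKM, -1.58) and IL1B (-1.57), with camera 1.74e-06 and adjusted p = 0.00851 with an estimated correlation. Of 27 interferon-stimulated genes, 14 were lower and 1 higher (16 and 3 over the list alone), such as GBP1 (-1.10) and OASL (-1.05), with camera 0.00371 and adjusted p = 0.037 with an estimated correlation. Of 26 p53 target genes, 13 were higher and none lower (15 over the list alone), with BTG2 (0.79) and CCNG1 (0.49) among them, camera 4.21e-05 and adjusted p = 0.00851 with an estimated correlation. Of 53 G2/M genes, 35 were higher and 2 lower (39 and 2 over the list alone), such as CENPF (1.09) and HMMR (0.75), with camera 6.2e-13 and adjusted p = 0.0468 with an estimated correlation. Of 30 unfolded protein and ATF4 response genes, 16 were lower and 6 higher by both adjustments, with SLC7A11 (-1.26), PHGDH (-0.95) and ASNS (-0.87) lower, camera 0.00813 and adjusted p = 0.049 with an estimated correlation. Of 10 replication-dependent histone genes, 4 were higher by both adjustments, such as HIST1H2BJ (0.92), with camera 0.00408 and adjusted p = 0.0468 with an estimated correlation.

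Further lists passed camera in untreated cells and were lost with an estimated correlation. Of 63 cytosolic ribosomal protein genes, 44 were higher and none lower (48 over the list alone), such as RPS6 (0.40), with camera 6.2e-13 and adjusted p = 0.17 with an estimated correlation. Of 22 TGF-beta target genes, 14 were lower and 1 higher by both adjustments, led by TAGLN (-1.28), with camera 0.00064 and adjusted p = 0.103 with an estimated correlation. Of 24 cholesterol biosynthesis genes, 11 were lower and 1 higher by both adjustments, led by MSMO1 (-0.44), with camera 0.0426 (0.0706 without WT untreated 1 and 0.0563 without KO untreated 2) and adjusted p = 0.0894 with an estimated correlation. Of 34 extracellular matrix genes, 17 were lower and 8 higher (17 and 9 over the list alone), with MMP1 (-1.79), MMP3 (-1.77) and DCN (-1.60) lower and THBS1 (1.21) higher. Camera gave 0.0479 for this list and adjusted p = 0.342 with an estimated correlation, and the camera call held only without KO untreated 1 or 2, KO SEMA3 2 or WT untreated 3, with 0.0508 to 0.165 (without KO untreated 3) in the 8 other fits that left out 1 library. Of 6 glial markers, 4 were higher and 1 lower by both adjustments, with SOX9 (1.14) and GJA1 (0.43) higher, camera 0.0479 (held only without KO untreated 1 or 2, WT untreated 1 or 2 or WT SEMA3 2, and 0.0521 to 0.0698 in the 7 other fits) and adjusted p = 0.117 with an estimated correlation.

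In all, 4451 genes passed the threshold between untreated KO and WT cells, 1977 higher and 2474 lower in KO, against 5717 at an unadjusted p under 0.05. The balance turned to 2289 higher and 2238 lower after quantile normalization and to 2798 and 2635 with the length and GC trend removed. How many lines or clones stand behind each genotype is not given in the sources used here, so a difference between lines that does not come from LATS1/2 cannot be told from one that does.

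With SEMA3 in both genotypes, KO cells again had more CYR61 (40.5 against 13.3 FPKM, 1.54, SE 0.04, adjusted p = 8.2e-10), CTGF (1.04), AMOTL2 (1.0), ANKRD1 (0.74) and AXL (0.72), and less WWTR1 (-0.48), while YAP1 (0.17, adjusted p = 0.11), NRP1 (0.08), NRP2 (-0.09) and PLXNA1 (-0.11) did not pass. UCA1 (2.59), MEST (2.45), FST (2.42), AL590369.1 (2.26), DKK1 (2.2), PADI2 (2.06), RGS4 (2.02) and CHRDL1 (1.96) were the highest in KO relative to WT. C3 (-3.51), ITGAX (-2.61), AL021977.1 (-2.15), CALB2 (-2.07), AKR1C1 (-2.03), CSF3 (-1.93), PDPN (-1.92) and ASS1 (-1.89) were the lowest. Of the genes called without SEMA3, 1254 of 1977 higher and 1752 of 2474 lower ones were called in the same direction with it, against 342.8 and 493.6 for independent lists. Another 108 were higher without SEMA3 and lower with it, and 5 the reverse. Both comparisons share a common estimate of the spread per gene, so the counts for independent lists are again only a rough reference. The log2 changes of both comparisons, which share no library, had a Pearson r of 0.697 and a Spearman correlation of 0.66 across genes, which are not independent replicates.

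Of 33 YAP/TAZ target genes, 25 were higher and 2 lower in KO with SEMA3 (26 and 2 over the list alone; camera 3.52e-13, and adjusted p = 0.00442 with an estimated correlation), led by IGFBP3 (1.58). NF-kB and inflammatory genes had 16 lower and 1 higher of 23 (17 and 1 over the list alone), with IL1B (-1.77) and CXCL8 (-1.37), camera 7.1e-06 and adjusted p = 0.00937 with an estimated correlation. Interferon-stimulated genes had 14 lower and 1 higher of 27 (17 and 1 over the list alone), with SAMD9 (-0.87), camera 8.28e-05 and adjusted p = 0.00937 with an estimated correlation. Among 26 p53 target genes, 14 were higher and 2 lower by both adjustments, with TIGAR (0.45), camera 0.00012 and adjusted p = 0.00937 with an estimated correlation. G2/M genes were mixed, with 25 higher, such as CCNB2 (0.53), and 6 lower, such as CENPE (-0.75) and KIF20B (-0.59), of 53 (28 and 6 over the list alone; camera 8.28e-05, and adjusted p = 0.239 with an estimated correlation).

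Of the 63 ribosomal protein genes, 45 were higher (49 over the list alone), such as RPSA (0.48), with camera 5.7e-14 and adjusted p = 0.218 with an estimated correlation. Glial markers had 4 higher and 1 lower of 6 by both adjustments, led by SOX9 (1.02), with camera 0.016 and adjusted p = 0.0938 with an estimated correlation. Neuronal markers had 3 lower of 4 by both adjustments, led by GAP43 (-0.84), with camera 0.0268 and adjusted p = 0.114 with an estimated correlation. Histone genes had 5 higher of 10 by both adjustments, with HIST1H1C (0.59), camera 0.0406 (0.0629 without KO SEMA3 3 and 0.0767 without WT SEMA3 1) and adjusted p = 0.118 with an estimated correlation. In all, 4931 genes passed the threshold, 2293 higher and 2638 lower in KO, against 6153 at an unadjusted p under 0.05. This balance depends on the scaling, with 2530 higher and 2438 lower after median-ratio scaling, 2722 and 2307 after quantile normalization, and 3101 and 2713 with the length and GC trend removed.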

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

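Tests chosen only after the result was seen were the term for the deeper libraries and both tests of falls in FPKM, while the removal of the length and GC trend was added after the data were seen, with its bounds set before its result.

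The results below stand out because the response to SEMA3 differed between WT and KO by the interaction test, which 291 genes passed. Of 100 splits of the libraries drawn from 200 possible ones, 2 gave at least 291 genes, the real one included. The other, with 919, exchanges the treatment labels in one genotype only and so adds the 2 effects by construction, and the highest of the rest was 28. The rest mix treated and untreated libraries in a group, so any SEMA3 effect widens the spread and lowers their counts. Low counts in them therefore do not decide whether the responses of the genotypes differ. The 2-group comparisons allow only 10 splits each, too few for a share under 0.05. In each, 1 of 10 splits, the real one, gave as many genes: 1103 against at most 1 in another split for SEMA3 in WT, 283 against 3 for SEMA3 in KO, 4451 against 3 for KO without SEMA3 and 4931 against 0 for KO with SEMA3. Here too the other splits mix the 2 groups, so any real difference widens the spread and lowers their counts. The gap between these counts and the real ones therefore adds no support.

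The first pattern is a more positive response in WT: CENPE (1.58), CENPF (1.5), GOLGA4 (1.5), ATRX (1.41), KIF20B (1.40), ASPM (1.34), ANKRD12 (1.34) and DST (1.26), with a G2/M list median of 0.027. Against more cells in G2 and mitosis, the 27 G2/M genes with shorter transcripts had a median of -0.046 (95% bootstrap interval -0.097 to 0.061), such as CCNB1 (-0.10), CDC20 (-0.11) and PLK1 (-0.10), which are named outside the rule. The 26 with longer transcripts had a median of 0.208 (-0.014 to 0.379). Both intervals treat genes as independent and leave out the spread between libraries, so they are too narrow. Transcript length and GC content may account for part of the first pattern: removing the length and GC trend left 202 of 247 calls (81.8%, interval 76.4 to 86.4, too narrow for the same reason, so not clearly above the bound of 80%) and moved the median from 0.60 to 0.46. The depth term left 83.7% of the median of the called genes (81.6 to 87.4, barely above 80%, with an interval too narrow because it treats genes as independent), 0.60 to 0.50 with a median SE of 0.094 and 0.096, and 122 of 248 genes stayed past the threshold. The interaction test found a difference between the change from untreated to SEMA3 libraries in WT and that change in KO. Whether it comes from a response that differs with genotype or from library differences that the labels do not map stays open. Such library differences, for example the index set, were not tested.

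The second pattern is the smaller log2 fall of YAP/TAZ target genes in KO, with a list median of -0.125 and interactions of -0.49 for CYR61 and -0.31 for CTGF. Only 4 of 33 members passed the threshold, and camera lost the list with an estimated correlation (adjusted p = 0.246), though fry kept it (adjusted p = 0.0111). For CYR61 and CTGF the log scale may be the cause: CYR61 fell by 15.3 FPKM in WT and 19.8 in KO, a difference of -4.49 (SE 1.2), and CTGF by 6.65 and 7.69, a difference of -1.04 (SE 0.44), so the fall in FPKM was larger in KO. As a share of the untreated mean, CYR61 fell by 53.5% in WT and 32.8% in KO, and CTGF by 47.1% and 31.9%. Untreated KO cells held more of both transcripts, so a larger fall in FPKM there does not decide between the scales. Other genes of the list were mixed: DLC1 had a difference of -4.5 (SE 0.9), AMOTL2 (-1.54, SE 1.4), AXL (2.57, SE 11) and ANKRD1 (0.126, SE 0.25) were undecided, and CRIM1 had 5.22 (SE 2.4), just over 2 SE. With 3 libraries per group and a bound set after the result, the CRIM1 value does not decide whether the log scale accounts for that gene. The length and GC trend does not account for CYR61, whose interaction was -0.40 (adjusted p = 0.001) with the trend removed. Loss of LATS1/2 stays open for these genes, as does any other difference between the lines, which was not tested.

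Among the 43 genes with a more negative response in WT, the others named for the largest differences were RP11-905K4.1 (-0.63), MMP3 (-0.60), HHIPL2 (-0.52), BTBD11 (-0.50), DKK1 (-0.49), F2R (-0.48) and APLN (-0.47). The TGF-beta target list had a median of -0.102 and the extracellular matrix list one of -0.108.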

How the results depend on the processing

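The term for libraries with HIDATA, the removal of the length and GC trend and the fit without small RNA genes were tests chosen only after the data were seen. No named gene or list past the threshold passed it in the opposite direction in an alternative run, but the balance of higher and lower genes turned in some, as the report gives for each contrast. Counts of genes moved by more than 1.5 times as follows, and the cause was not tested. SEMA3 in WT had 694 genes with no filter and 3879 with array weights. SEMA3 in KO had 176 with the replicate number as a block, 1220 with array weights, 109 with the HIDATA term, 494 with the length and GC trend removed and 21 with only the groups compared. The interaction had 2514 with array weights and 144 with the HIDATA term. Of 38 list results past camera, 14 passed with an estimated correlation. With fry, 4 list results past camera were lost and 21 others were gained. Leaving out 1 library gave 465 to 2124 genes for SEMA3 in WT, 82 to 372 in KO, 163 to 1240 for the interaction, 3554 to 4724 for KO without SEMA3, 3872 to 5693 for KO with SEMA3 and 32 to 44 lists. The KO contrasts kept their counts within 1.5 times in every alternative.

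The replicate numbers showed no clear pairing over all groups: 5 of 18 pairs with the same number had a correlation of deviations above 0.1 (-0.265 to 0.293), and 5 of 12 libraries correlated best with their own number. Pairs with other numbers, over all groups, went from -0.276 (KO SEMA3 1 with WT SEMA3 3) to 0.407 (KO SEMA3 1 with WT SEMA3 2). Between untreated and treated WT libraries the same-number values were 0.129, 0.293 and 0.031, against -0.262 to 0.169 for other numbers. In KO the same-number values were -0.031, 0.054 and 0.004. A pairing within WT therefore stays open. With the block, SEMA3 in WT had 962 genes, the interaction 253, KO without SEMA3 4387 and KO with SEMA3 4860, while SEMA3 in KO fell from 283 to 176. A count test was not run, since no counts were used. The depth behind each value is unknown, and at an FPKM from 1 to 5 confidence bounds with a median distance of 19.5% to 23.6% limit what a single library shows.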

Other observations

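All values here are descriptions, and no test in this part was chosen after its result was seen. Several receptor genes for class 3 semaphorins were expressed. NRP1 had 188 ± 2.5 FPKM in untreated WT and 194 ± 8.0 in untreated KO cells, NRP2 52.1 ± 0.82 and 48.8 ± 1.6, and PLXNA1 10.4 ± 0.90 and 9.66 ± 0.82. PLXNA2 was 3.85 ± 0.20 in WT and 1.96 ± 0.11 in KO (-0.71, adjusted p = 3.6e-05), and PLXND1 was 3.06 ± 0.31 and 1.27 ± 0.31 (-0.85, adjusted p = 0.00034). The cells also expressed the ligands themselves: untreated WT cells had 46.2 ± 4.1 FPKM of SEMA3C and 10.6 ± 1.2 of SEMA3A, and untreated KO cells had 58.7 ± 0.43 and 7.46 ± 1.2 (0.34, adjusted p = 0.0017, and -0.46, adjusted p = 0.0069). None of the 3 tested ligand genes passed the threshold after SEMA3 in WT or KO.

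Glial markers were mixed in this line, with 6 of 14 tested. VIM had 3510 FPKM, CD44 591, GJA1 60.0, SLC1A3 11.8 and NES 4.63 in untreated WT cells, whereas GFAP had 0.255 and its highest library 0.52, and AQP4 was listed at 0 in all 12 libraries. Of markers of other cell types, CD68 (266 FPKM), CD74 (143) and HLA-DRA (77.5) were high in untreated WT cells, as were the neuronal TUBB3 (119) and SNAP25 (12.8), and the epithelial KRT8 had 5.51 and EPCAM 1.66. PTPRC did not exceed 0.268 in any library, CDH1 0.0987 and VWF 0.116. CSF1R was 17.1 ± 2.0 in untreated WT and 8.98 ± 0.92 in untreated KO cells (-0.86, adjusted p = 2.5e-05). Mitochondrially encoded genes are listed at 0 and were not tested.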
